A study of Mus musculus with 11 samples.

How the data were processed

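The series holds 11 RNA-seq libraries of sorted mouse ST-HSCs, with 3 WT vehicle, 2 KO vehicle, 3 WT treated and 3 KO treated libraries. The sample titles read Cre_neg for the libraries called WT here and Cre_pos for those called KO. Per the submitters' processing notes, RNA from an RNeasy Plus Micro kit was amplified with the SMARTer Ultra Low Input kit and made into libraries with Nextera XT, and the tools named without roles were bcl2fastq, Trim Galore 0.6.7, STAR 2.7.9a, HTSeq (listed as 0.6.7) and DESeq2, with genome build GRCm39. The deposited table holds raw read counts per Ensembl gene, as whole numbers with no normalization by the authors, for 53700 genes and 5 HTSeq summary lines. The annotation release, the strand setting and any filters are not stated. The kits do not keep the strand, so reads of overlapping genes on opposite strands may be set aside as ambiguous or counted for the wrong gene. The ambiguous line held 2.34% (240) to 6.31% (262) of all reads. The summary lines were left out of the counts tested. Reads outside annotated genes were 5.98% (276) to 30.4% (257) of all reads in the table, and reads at more than 1 place were 11.6% (262) to 30.0% (257).

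Gene IDs were matched by their stable part to a mouse GENCODE reference of an earlier build, which gave symbols for 52093 of the 53700 genes and transcript lengths for 99.7% of the genes tested. No coordinates are given, since the reference and the deposited counts are on different builds. Depth ran from 8.13 to 31.1 M gene counts per library. Counts carry no molecular identifiers, so the floor of 3 counts used for groups at 0 covers counting error only.

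Testing was done in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the 4 groups (16639 genes), libraries were scaled with TMM, and 1 model with the 4 groups was fitted by quasi-likelihood with the robust option. The biological coefficient of variation was 0.783. No term for pairing or batch was used, since the labels give neither. There were 7 contrasts: KO against WT in treated and in vehicle hosts, treated against vehicle in the WT and the KO niche, the interaction, and the mean niche and mean treatment effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. SE values are the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic, so they follow from the test. CPM values use TMM-scaled library sizes.

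The 34 gene lists were fixed before the data were examined, as were the samples' groups, the main tests, the naming rule and the first alternatives. They hold 979 gene names, of which 976 matched the table. They cover p38 MAPK, the CXCL12/CXCR4 axis, FLT3/STAT5 targets, stem cell genes, AP-1 immediate early genes, ERK output, NF-kB, p53 targets, quiescence and CDK inhibitors, S phase, G2/M, MYC and ribosome assembly, ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, glycolysis and hypoxia, NRF2, ATF4, heat shock, BCL2 family, DNA repair, drug handling, TGF-beta and BMP, type I interferon and antigen presentation. They also cover markers of granulocytes, monocytes, mast cells, erythroid cells, megakaryocytes, B cells, T and NK cells and stroma or endothelium, and sex-linked genes. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. A list score is the mean log2 CPM of its members in a library.

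The genes named in the text come from a rule set in advance. For each contrast it takes, among genes past the threshold with groups that do not overlap, a mean log2 CPM of at least 3 and a symbol that is not a predicted model, the 12 largest changes each way. It adds up to 4 members of each list with the smallest p, Cxcl12, Cxcr4, Tet2, Flt3, Mapk14, Cdkn1a and Mki67 always, and the 10 genes with the smallest p where fewer than 10 pass. The text gives a part of these.

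Alternatives set in advance were DESeq2 size factors and upper-quartile scaling, no filter and a filter at a mean CPM of 10, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no robust option, only the libraries compared, and leaving out each library in turn. Where a library of the KO vehicle group was left out, the lone one was assumed to vary like the other groups. Alternatives chosen after the data were seen were leaving out 253 and 265 together, the share of reads outside genes as a covariate, removing the trend of each library with transcript length (a lowess fit with span 0.3, as an offset) with and without library 257, and an exact permutation of list scores.

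The pipeline was tested on simulated counts with the estimated spread, with 100 genes changed 4-fold and 100 changed 16-fold. For KO against WT in treated hosts, edgeR recovered 30% and 93% of them with 3 false calls, limma voom 24% and 81% with 4, and DESeq2 52% and 100% with 95. For treatment in the WT niche, edgeR recovered 32% and 81% with 5 false calls, limma voom 26% and 67% with 2, and DESeq2 60% and 94% with 117. For the mean niche effect, edgeR recovered 60% and 96% with 8 false calls, limma voom 50% and 92% with 8, and DESeq2 84% and 100% with 103. With 0.25 of the estimated spread, edgeR recovered 93%, 95% and 95% of the 4-fold changes in these contrasts, with 8, 10 and 11 false calls, and DESeq2 97%, 98% and 98% with 58, 67 and 62. The simulated counts were drawn independently for each gene and library. They held no structure shared between libraries, so these rates may not hold for the real data.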

Results

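Bulk RNA sequencing measured gene expression in short-term haematopoietic stem cells (ST-HSCs) sorted from mouse bone marrow. The host mice had been transplanted with marrow of an acute myeloid leukaemia that carried the Flt3-ITD mutation and lacked Tet2. By description, the hosts' own marrow environment (niche) either had the chemokine Cxcl12 (WT, titled Cre_neg) or lacked it (KO, titled Cre_pos). Hosts received vehicle or a combination of cytarabine and doxorubicin, which damage or block the copying of DNA, with quizartinib, an inhibitor of the FLT3 kinase. The 11 libraries formed 4 groups: 3 WT vehicle (240, 253 and 265), 2 KO vehicle (249 and 275), 3 WT treated (252, 262 and 266) and 3 KO treated (257, 263 and 276). Counts assigned to genes were 17.0, 20.4 and 8.13 M in the WT vehicle libraries and 19.6 and 22.2 M in the KO vehicle libraries. They were 31.1, 22.4 and 25.0 M in the WT treated libraries and 25.5, 25.6 and 26.4 M in the KO treated libraries, in the order named. The labels do not state that the libraries came from separate animals, so p-values measure only the spread between these samples.

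The label's factor itself could not be read from these cells, since the title of the series places the deletion in the microenvironment. How complete the deletion was is not known, and the presence of Cre cannot be told apart from it. Cxcl12 transcripts in the sorted cells were at 2.91 CPM ± 1.71 (counts scaled to library size, SD, n = 3) in KO treated and 1.09 CPM ± 0.428 (n = 3) in WT treated libraries, a log2 fold change of 1.41 ± 1.96 (SE) with an edgeR adjusted p of 0.873. Cxcr4, its receptor, was at 52.2 CPM ± 26.2 and 64.7 CPM ± 9.82 in the same groups. Tet2, which the leukaemia lacked by its description, was at 18.9 CPM ± 13.9 and 16.1 CPM ± 6.61, and Flt3 at 131 CPM ± 80.5 and 186 CPM ± 71.3. None of the last 3 genes passed the test (adjusted p = 0.906, 0.953 and 0.838).

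The libraries differed in ways that no label records. Every treated library had more gene counts (22.4 M or more) than any vehicle library (22.2 M or less), so depth cannot be told apart from treatment. Between 13589 (253) and 22121 (252) genes had a count, and WT vehicle libraries 253 and 265 lay apart from the other 9 on the first 2 principal components, which held 31.8% and 16.9% of the variance. Counts from mitochondrial genes took 2.08% (262) to 19.8% (240) of each library. Globin genes took 3.97%, 2.84% and 10.5% in KO treated libraries 257, 263 and 276 and 1.83% in KO vehicle library 275, against 0.0998% or less in the other 7. Across genes, the expression of a library relative to the mean of all libraries ran with transcript length at a Spearman rho of -0.34, -0.59 and -0.56 in the WT treated libraries and -0.31 in KO treated 257, and from 0.11 to 0.57 in the other 7 (genes are not independent replicates).

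The comparison named in the series title asks how the niche factor alters leukaemic stem cells under therapy. Whether the sorted cells were leukaemic or of the host was not tested. Granulocyte list scores (mean log2 CPM) averaged 8.58, 8.73, 8.38 and 7.63 in WT vehicle, KO vehicle, WT treated and KO treated libraries. Those of the haematopoietic stem cell list averaged 2.75, 3.83, 3.92 and 4.32. The lists hold different genes, so their scores give no share of cells. Shifts in any list may reflect other cells in the sort as well as changes within stem cells, which was not tested. In treated hosts, genes of the red-cell lineage were higher with the KO niche: all 19 measured members of the erythroid list had a positive log2 fold change, with a median of 5.84. Alas2, which starts haem synthesis in red-cell precursors, was at 1247 CPM ± 1499 (SD, n = 3) in KO and 3.89 CPM ± 1.18 (n = 3) in WT libraries, a log2 fold change of 8.33 ± 1.65 (SE). Slc4a1, the anion exchanger of the red-cell membrane, was at 487 CPM ± 640 and 1.03 CPM ± 0.509. Rhd, a red-cell surface protein, was at 230 CPM ± 211 and 3.12 CPM ± 1.37, and Blvrb, a reductase of red cells, at 375 CPM ± 237 and 34.2 CPM ± 5.22. Outside the list, Trim10 (ENSMUSG00000073400.7), which acts in red-cell maturation, had the smallest p of all genes, at 157 CPM ± 185 and 0.420 CPM ± 0.322. Add2 and Epb41, both of the red-cell membrane skeleton, had log2 fold changes of 6.39 ± 1.14 and 3.69 ± 0.74, and Ube2o, a ubiquitin ligase of maturing red cells, 4.34 ± 0.77. The erythroid list rose with the camera test at a preset correlation (adjusted p = 7.51e-29) and not with an estimated correlation (adjusted p = 0.311). Within it, 18 genes passed when adjusted over the list alone and 0 when adjusted over all genes tested. In 18 of the 19 genes each KO treated library was above every WT treated library.

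**Figure D1:**
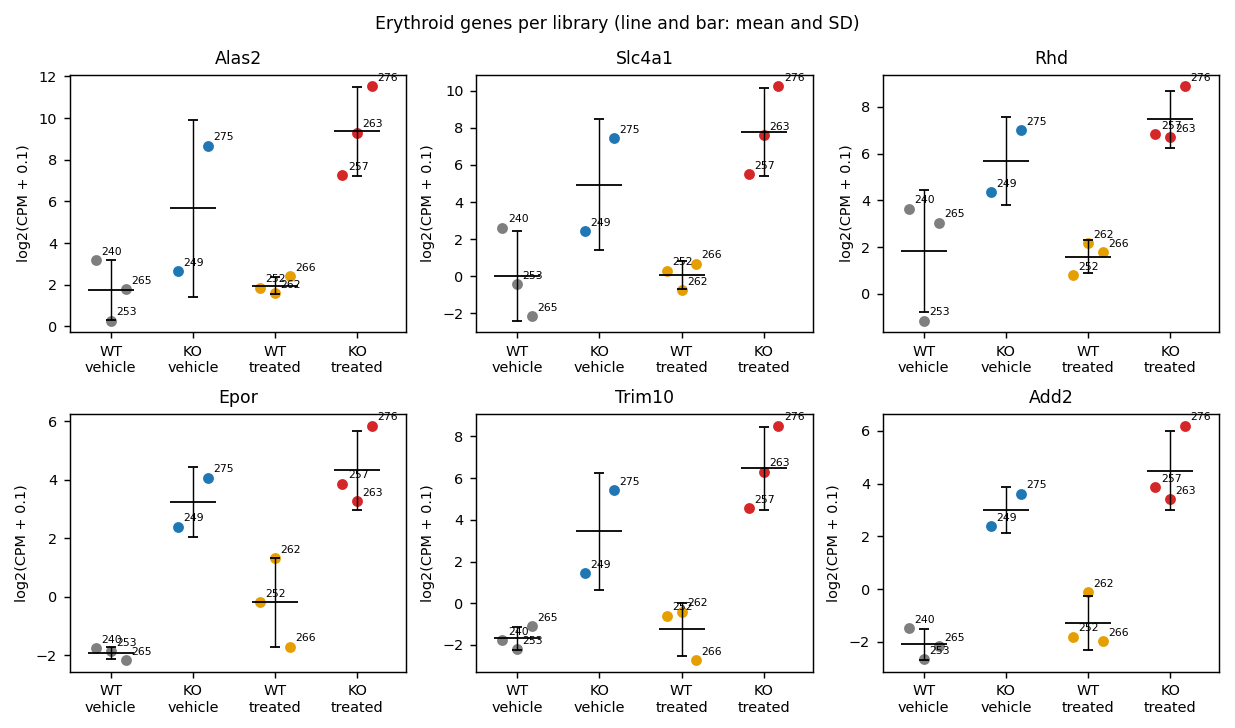
Expression of 6 genes of the red-cell lineage in each library, as log2(CPM + 0.1), by group. Points are libraries, lines are group means and bars are SD. The 3 KO treated libraries lie above the 3 WT treated libraries for Alas2, Slc4a1, Rhd, Trim10 and Add2.

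Other gene groups differed between the treated niches by smaller steps, and the scores of the 4 lists below overlapped between the 2 groups of libraries. Nuclear genes for oxidative phosphorylation were lower with the KO niche, with a median log2 fold change of -0.59 and 69 of 71 members negative. Among them, Ndufa9 and Sdhb of respiratory complexes had log2 fold changes of -1.01 ± 0.30 and -1.06 ± 0.32, and Cycs, which encodes cytochrome c, -1.09 ± 0.38. Ribosomal protein genes had a median of -0.38 (67 of 76 negative), with Rpl34 at -0.91 ± 0.41. KO treated 257 went the other way in both lists. Its scores of 8.38 and 9.87 lay above every WT treated library (8.07 to 8.27 and 9.03 to 9.55), with 263 and 276 below (6.84 and 6.96, and 8.10 and 7.69). The antigen presentation list had a median of -0.58 (27 of 37 negative). H2-Ab1, a class II molecule, was at 1162 CPM ± 632 in KO and 5779 CPM ± 3100 in WT libraries, and H2-K1, a class I molecule, at 1125 CPM ± 143 and 2079 CPM ± 376. Granulocyte genes had a median of -0.98 (18 of 27 negative), and Ngp, Chil3 and Fcnb, made by developing neutrophils, had log2 fold changes of -3.24 ± 0.98, -3.45 ± 0.91 and -2.79 ± 0.70. These 4 lists fell with the preset correlation (adjusted p = 3.36e-16, 1.24e-09, 5.84e-05 and 0.000306) and each had an adjusted p of 0.822 with an estimated correlation. Of the granulocyte genes 2 passed when adjusted over the list alone and none of the other 3 lists held any, and 0 passed over all genes. The medians moved with single libraries: without KO treated 257 they were -1.39 for oxidative phosphorylation and -1.43 for ribosomal proteins, and without KO treated 263 or 276 they were -0.26 or -0.34 and -0.08 or -0.01. Without WT treated 252 the ribosomal and antigen presentation medians were -0.19 and -0.34, and without WT treated 266 the granulocyte call ended (median -0.57, adjusted p = 0.228). With the transcript length trend removed, the oxidative phosphorylation and ribosomal medians were -0.28 and -0.09.

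DNA repair and drug handling genes were higher with the KO niche in treated hosts. DNA repair had a median log2 fold change of 0.60 (34 of 43 positive), with Parp1, a sensor of strand breaks, at 179 CPM ± 59.3 in KO and 82.2 CPM ± 2.55 in WT libraries and Msh6, of mismatch repair, at 100 CPM ± 67.8 and 29.5 CPM ± 5.58. The drug handling list had a median of 0.72 (18 of 24 positive). Its members Top2b, a target of doxorubicin, Abcg2, an efflux pump, and Aldh1a1, an aldehyde dehydrogenase, had log2 fold changes of 1.37 ± 0.38, 1.91 ± 0.57 and 3.91 ± 1.02. Abcb4, a transporter related to drug efflux pumps, was at 30.5 CPM ± 19.3 in KO and 1.99 CPM ± 0.834 in WT libraries. The list of stromal and endothelial markers, most of which a sorted stem cell should not express strongly, had a median of 2.09 (13 of 16 positive). Its scores were low, from 0.0085 to 1.31 in KO treated and from -0.80 to -0.18 in WT treated libraries. These 3 lists rose with the preset correlation (adjusted p = 0.00124, 0.0117 and 0.0302), and each had an adjusted p of 0.822 with an estimated correlation. Of the drug handling genes 3 passed when adjusted over the list alone, none of the other lists held any, and 0 passed over all genes. The DNA repair and drug handling calls ended with the length trend removed (adjusted p = 0.0873 and 0.135). The drug handling call also ended without KO treated 276 (median 0.15, adjusted p = 0.0852), and the stromal call ended without WT treated 262 (0.0866) or KO treated 257 (median 1.17, adjusted p = 0.261) and with the share of reads outside genes as a covariate (0.0684).

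The series title places p38 MAPK signalling downstream of the niche factor, and transcript levels do not measure kinase activity. Mapk14, the gene for p38 alpha (ENSMUSG00000053436.16), was at 153 CPM ± 68.9 in KO treated and 74.7 CPM ± 8.38 in WT treated libraries, a log2 fold change of 1.03 ± 0.37, or 0.64 with the length trend removed. Mknk2, a kinase downstream of p38, and Tab1, an activator of p38 alpha, had log2 fold changes of 1.37 ± 0.37 and 1.22 ± 0.39. The p38 list had a median of 0.47, with 27 of 38 members positive, and did not pass (adjusted p = 0.111 preset and 0.822 with an estimated correlation). Without KO treated 257 or WT treated 266 it passed with the preset correlation (median 0.82 and 0.54, adjusted p = 0.00935 and 0.0215), as it did with the share of reads outside genes as a covariate (0.52, adjusted p = 0.023). Cdkn1a, the cell cycle inhibitor p21, was at 40.3 CPM ± 33.8 and 66.3 CPM ± 12.3, and the proliferation marker Mki67 at 248 CPM ± 69.5 and 150 CPM ± 29.3.

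By gene, edgeR's quasi-likelihood test called 0 of 16639 genes between the treated niches, with a smallest adjusted p of 0.379. At an unadjusted p under 0.05 there were 1769 genes (10.6% of those tested). DESeq2 called 226 genes (201 higher, 25 lower) and limma voom with quality weights 4375 (2368 higher, 2007 lower). Without KO treated library 257, edgeR called 1513 genes (716 higher, 797 lower), and with the length trend removed as well 43 (6 higher, 37 lower). The 2 groups did not overlap for 19.3% of genes, against 10% by chance on average over all splits of 3 libraries against 3. Genes vary together, so the share can differ widely between splits, and an excess over chance was not tested.

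**Figure D2:**
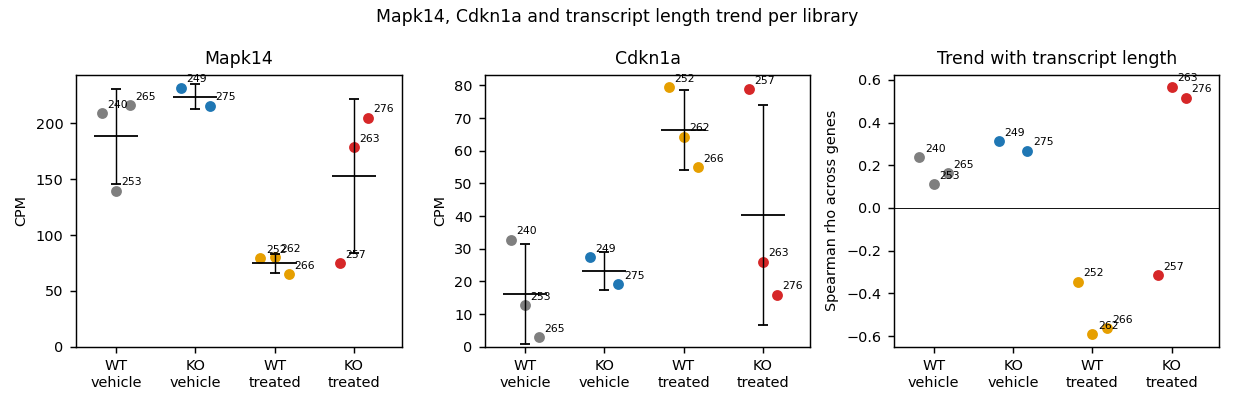
Mapk14 and Cdkn1a in CPM, and the Spearman rho between transcript length and relative expression across genes, for each library by group. Points are libraries, and lines and bars in the first 2 panels are group mean and SD. KO treated library 257 lies within the range of the WT treated libraries for Mapk14 and Cdkn1a, and its rho of -0.31 is next to their -0.34 to -0.59.

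The comparison of niches in vehicle hosts asks what the niche factor does without therapy. Erythroid genes were again higher with the KO niche: 19 of 19 were positive, with a median log2 fold change of 2.65. Epor, the erythropoietin receptor, was at 10.9 CPM ± 8.14 (SD, n = 2) in KO and 0.164 CPM ± 0.0366 (n = 3) in WT libraries, and Trim10 and Add2 had log2 fold changes of 6.77 ± 1.47 and 5.81 ± 1.20. Alas2 was at 207 CPM ± 284 and 4.47 CPM ± 4.06, and Slc4a1 at 89.9 CPM ± 120 and 2.26 CPM ± 3.26, with most of the KO signal in library 275. Megakaryocyte and platelet genes had a median of 2.15, which stayed at 2.15 with the 4 members at 0 in a group set to a floor of 3 counts over that group, and 17 of 18 were positive. Pf4, a platelet chemokine, was at 127 CPM ± 177 and 6.11 CPM ± 2.50, with a log2 fold change of 4.38 ± 1.31 that turned to -1.46 without library 275. Clu, a secreted chaperone, was at 34.3 CPM ± 21.3 and 0.424 CPM ± 0.590, and Slc38a5, an amino acid transporter, at 18.2 CPM ± 4.71 and 0.384 CPM ± 0.508. Both lists rose with the preset correlation (adjusted p = 3.24e-12 and 1.85e-06), and both had an adjusted p of 0.838 with an estimated correlation. Adjusted over the list alone, 8 erythroid and 6 megakaryocyte genes passed, and 0 passed over all genes. Without KO vehicle 275 the erythroid median was 0.55, and the megakaryocyte call ended with a median of 0.50 (adjusted p = 0.0654). Without WT vehicle 240 the megakaryocyte median was 5.24.

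Ribosomal protein genes were lower with the KO niche in vehicle hosts, with a median log2 fold change of -0.59 and 74 of 76 negative, and all 13 mitochondrially encoded genes were negative, with a median of -1.24. Immediate early genes of the AP-1 family had a median of -0.62 (-0.67 with members at 0 in a group at their bound). Fos was at 179 CPM ± 29.2 in KO and 474 CPM ± 12.7 in WT libraries. Genes of MYC-driven ribosome assembly had a median of 0.40 (34 of 38 positive), with Rrs1 at 78.5 CPM ± 3.85 and 43.1 CPM ± 2.76 and Rrp12 at 48.8 CPM ± 8.19 and 21.1 CPM ± 2.75. The ATF4 and unfolded protein list had a median of 0.42, with Asns, which makes asparagine, at 60.5 CPM ± 13.4 and 25.0 CPM ± 7.23. Mapk14 was at 224 CPM ± 11.3 and 188 CPM ± 42.4, a log2 fold change of 0.25 ± 0.40 that turned to -0.16 with the share of reads outside genes as a covariate and to -0.16 with the length trend removed. The first 3 lists fell and the last 2 rose with the preset correlation (adjusted p = 3.24e-12, 3.63e-06, 1.02e-05, 0.00487 and 0.0177). With an estimated correlation the adjusted p was 0.902, 0.902, 0.838, 0.902 and 0.838, and 0 members of these 5 lists passed when adjusted over the list alone or over all genes. The ribosome assembly call ended without WT vehicle 240 (adjusted p = 0.351) or KO vehicle 249 (median 0.20, adjusted p = 0.654). The ATF4 call ended without WT vehicle 240 (0.122), WT vehicle 265 (0.0720) or KO vehicle 275 (0.13), and its median was 0.69 without KO vehicle 249. It ended too without both 253 and 265 (0.0564). Both calls also ended with the length trend removed (adjusted p = 0.414 and 0.1). With the share of reads outside genes as a covariate, the ribosomal median turned to 0.16 and the ribosomal, mitochondrially encoded and ATF4 calls ended (adjusted p = 0.698, 0.0733 and 0.187).

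By gene, edgeR called 0 of 16639 genes between the vehicle niches, with a smallest adjusted p of 0.267, and 1128 genes had an unadjusted p under 0.05. DESeq2 called 206 genes (165 higher, 41 lower) and limma voom 0. Without WT vehicle library 240, edgeR called 85 genes, all higher. The groups did not overlap for 20.7% of genes, against 20% by chance on average over all splits of 3 libraries against 2.

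Averaged over treatment, the niche comparison used all 11 libraries, and 14 of the 34 lists passed camera with the preset correlation, 8 higher and 6 lower, against 0 with an estimated correlation (smallest adjusted p 0.31), 0 with fry and 0 by permutation. The erythroid list had a median log2 fold change of 4.49, with 19 of 19 members positive, and Trim10 and Add2 had log2 fold changes of 7.62 ± 1.02 and 6.10 ± 0.83 with an adjusted p of 0.0874. Epor, Alas2, Rhd, Slc4a1 and Rhag, a red-cell ammonia channel, had values of 5.28 ± 0.81, 6.92 ± 1.11, 4.82 ± 0.82, 7.07 ± 1.22 and 5.24 ± 0.94. The list rose with the preset correlation (adjusted p = 1.25e-32). The adjusted p was 0.31 with an estimated correlation. All 19 genes passed when adjusted over the list alone and 0 over all genes. An exact permutation of the mean erythroid score of each library within treatment gave a two-sided p of 0.005, the smallest that 200 arrangements can give, and 0.132 after adjustment over 34 lists. At that p a list cannot pass over 34 lists unless others also reach small p-values. DNA repair rose with a median of 0.46 (adjusted p = 0.00174), and the p38 list rose with a median of 0.54 (0.0369), or 0.49 without the 3 members at 0 in a group. Both had an adjusted p of 0.69 with an estimated correlation, and with the length trend removed their medians were 0.08 and 0.01 and neither passed. Without KO treated 276 the DNA repair median was 0.30. The p38 call ended without 240, 265, 252, 262, 263 or 276 (adjusted p from 0.0646 to 0.138), with a median of 0.30 without 276, with upper-quartile scaling (0.063) and with the share of reads outside genes as a covariate (0.122). Mapk14 had a log2 fold change of 0.64 ± 0.27, or 0.24 with the length trend removed. By gene, edgeR called 0 of 16639 (smallest adjusted p 0.0874, with 1811 genes at an unadjusted p under 0.05), DESeq2 371 (315 higher, 56 lower) and limma voom 545 (335 higher, 210 lower). Without 257, edgeR called 1000 genes (489 higher, 511 lower), and with the length trend removed as well 74 (20 higher, 54 lower). Without 240 or 249 it called 108 or 23, all higher.

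Another 11 lists passed for the averaged niche effect, 6 of them lower. Ribosomal protein, nuclear oxidative phosphorylation, AP-1, antigen presentation, granulocyte and monocyte genes fell with the preset correlation, with medians of -0.52, -0.37, -0.39, -0.58, -0.28 and -0.50 (adjusted p = 2.86e-17, 2.66e-10, 0.000336, 0.000416, 0.0185 and 0.0317). Megakaryocyte, MYC ribosome assembly, drug handling, G2/M and S phase genes rose, with medians of 1.58 (1.09 without the 4 members at 0 in a group), 0.20, 0.56, 0.33 and 0.25 (adjusted p = 0.000241, 0.0277, 0.0346, 0.0369 and 0.0464). The adjusted p with an estimated correlation was 0.776 for G2/M and 0.69 for each of the others. When adjusted over the list alone, 3 granulocyte, 2 ribosome assembly and 1 drug handling gene passed, none of the other 8 lists held any, and 0 passed over all genes. Without 257, 263 or 276 the ribosomal median was -1.02, -0.34 or -0.31 and the oxidative phosphorylation median -0.74, -0.20 or -0.22. Without 240 the AP-1 median was -0.25 and the antigen presentation call ended (median -0.26, adjusted p = 0.138), and without 275 the megakaryocyte call ended (median 0.50, adjusted p = 0.11). The granulocyte call ended without 253, 249, 266, 257 or 263 (adjusted p from 0.0583 to 0.535), with medians of -0.01 without 266, -0.70 without 275 and -0.55 without 276. The monocyte call ended without 240, 253, 249, 266, 257 or 263 (0.0675 to 0.68), with medians of -0.19 without 249 and -0.79 without 275. The ribosome assembly call ended without 240, 253, 249, 266 or 257 (0.0541 to 0.358), with a median of 0.11 without 249, and the drug handling call without 240, 253, 265, 249 or 276 (0.0513 to 0.138), with a median of 0.29 without 276. The G2/M call ended without 240, 265, 275, 252 or 276 (0.0836 to 0.444), with medians of 0.16 without 265, 0.13 without 276 and 0.51 without 253, and the S phase call without 240, 265, 249, 252 or 276 (0.0864 to 0.399). With the length trend removed the granulocyte, monocyte, ribosome assembly, drug handling, G2/M and S phase calls ended (0.158, 0.0673, 0.196, 0.36, 0.705 and 0.575). Upper-quartile scaling ended the ribosome assembly, G2/M and S phase calls (0.0708, 0.0708 and 0.0906), DESeq2 size factors the G2/M and S phase calls (0.0529 and 0.0653), the covariate the G2/M call (0.119), and leaving out 253 and 265 the drug handling and granulocyte calls (0.125 and 0.876).

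Treatment in the WT niche compares the sorted cells after therapy with the WT vehicle libraries, which did not resemble one another. Nuclear oxidative phosphorylation genes were higher after treatment, with a median log2 fold change of 1.08 (66 of 71 positive). Cycs was at 404 CPM ± 50.1 (SD, n = 3) after treatment and 112 CPM ± 10.2 (n = 3) with vehicle, and Sdhb and Ndufa1 had log2 fold changes of 1.52 ± 0.33 and 1.37 ± 0.38. Ribosomal protein genes had a median of 0.80 (75 of 76 positive), with Rps18 at 1704 CPM ± 439 and 613 CPM ± 44.7 and Rps14 at 1.39 ± 0.48 on the log2 scale. The 13 mitochondrially encoded genes went the other way, with a median of -1.44 and all 13 negative, and mt-Nd5 was at 3694 CPM ± 4444 and 14245 CPM ± 3191. Glycolysis and hypoxia genes were lower, with a median of -0.77 (22 of 31 negative). Hk1, the first enzyme of glycolysis, was at 35.1 CPM ± 2.33 and 103 CPM ± 25.2, and Pfkl and P4ha1 had log2 fold changes of -1.32 ± 0.39 and -1.34 ± 0.40. With the preset correlation the first 2 lists rose (adjusted p = 7.28e-13 and 2.33e-06) and the other 2 fell (3.46e-08 and 8.99e-06). Their adjusted p with an estimated correlation was 0.759, 0.838, 0.759 and 0.745, in the order given. Adjusted over the list alone, 15 oxidative phosphorylation and 4 glycolysis genes passed and none of the other lists held any, and 0 passed over all genes. With the length trend removed the oxidative phosphorylation median was 0.14 and the ribosomal median turned to -0.18, and neither passed (adjusted p = 0.149 and 0.724). Without WT treated 266 the mitochondrially encoded median was -3.07. Without both WT vehicle 253 and 265 the glycolysis call ended (median -0.18, adjusted p = 0.127), and with the share of reads outside genes as a covariate the mitochondrially encoded call ended (median -0.79, adjusted p = 0.0706).

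The B lymphoid, antigen presentation and type I interferon lists were also higher after treatment in the WT niche. The T and NK list did not pass there (median 1.53, or 0.36 without the 7 members at 0 in a group, adjusted p = 0.112 preset and 0.759 with an estimated correlation). The B lymphoid list had a median log2 fold change of 3.69, or 3.0 with 5 members at 0 in a group at their bound, and 18 of 19 were positive. Its scores were low, from -0.82 to -0.08 in WT vehicle and from 1.52 to 2.50 in WT treated libraries. The treated libraries were also deeper, and the part of depth in this rise was not tested. Blnk, an adaptor of the B-cell receptor, was at 4.75 CPM ± 1.26 after treatment and 0.149 CPM ± 0.163 with vehicle, and Igkc, an immunoglobulin light chain, at 95.4 CPM ± 74.0 and 12.5 CPM ± 6.09. The list rose with the preset correlation (adjusted p = 0.00011) and with fry, which asks whether its genes moved one way (0.0195), and had an adjusted p of 0.58 with an estimated correlation. Of its genes 6 passed when adjusted over the list alone, and 0 over all genes. Without WT vehicle 240 its median was 5.66, and with the share of reads outside genes as a covariate its call ended (adjusted p = 0.0723). Antigen presentation had a median of 0.77 and type I interferon genes 0.79, with Psmb9, of the immunoproteasome, at 661 CPM ± 206 and 187 CPM ± 59.8, B2m at 5306 CPM ± 715 and 2026 CPM ± 666, and Bst2 at 239 CPM ± 86.6 and 66.3 CPM ± 27.2. Ly6e had a log2 fold change of 1.20 ± 0.38. Both rose with the preset correlation (adjusted p = 0.00395 and 0.0435), had an adjusted p of 0.77 and 0.838 with an estimated correlation, and held 0 genes that passed over the list alone or over all genes. The antigen presentation call ended without 265 (0.0961) or 252 (median 0.40, adjusted p = 0.0828), and its median was 1.43 without 240. The interferon call ended without 253, 265, 249, 252 or 257 (adjusted p from 0.0545 to 0.436), with a median of -0.21 without 252, 0.21 without 253 and 0.43 without 265, and its median was 1.77 without 240 and 1.20 without 266. It ended with upper-quartile scaling as well (0.0773). Both calls ended without 253 and 265 together (0.775 and 0.0745), where the interferon median turned to -0.43, and with the share of reads outside genes as a covariate (0.0706 and 0.166).

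Lists of kinase pathways and DNA repair were tested for treatment in the WT niche as well. Mapk14 was at 74.7 CPM ± 8.38 after treatment and 188 CPM ± 42.4 with vehicle, a log2 fold change of -1.33 ± 0.37. Map2k4, a kinase upstream of p38, and Mapkapk2, its substrate kinase, had log2 fold changes of -1.48 ± 0.44 and -1.49 ± 0.45. Stat5a and Stat5b, the transcription factors that Flt3-ITD activates, were at 20.7 CPM ± 6.03 and 25.9 CPM ± 5.78 after treatment and 86.3 CPM ± 49.8 and 82.2 CPM ± 16.6 with vehicle. Pik3cd and Jak3, of the CXCL12/CXCR4 list, had log2 fold changes of -1.49 ± 0.34 and -1.97 ± 0.60. In the DNA repair list, Parp1 had a value of -0.93 ± 0.32. Cdkn1a was at 66.3 CPM ± 12.3 after treatment and 16.1 CPM ± 15.2 with vehicle, and Mki67 at 150 CPM ± 29.3 and 223 CPM ± 30.3. The CXCL12/CXCR4, FLT3/STAT5, p38 and DNA repair lists had medians of -0.63, -0.73, -0.44 and -0.44 and fell with the preset correlation (adjusted p = 0.000247, 0.0335, 0.0335 and 0.0362), although the mean of the p38 list was 0.37 and the list scores of p38 and DNA repair were higher after treatment, by 0.18 and 0.13. Each had an adjusted p of 0.759 with an estimated correlation. Adjusted over the list alone, 1 CXCL12/CXCR4 and 2 FLT3/STAT5 genes passed, none of the others did, and 0 passed over all genes. The FLT3/STAT5 call ended without 240, 253 or 252 (adjusted p from 0.0598 to 0.135), with a median of -0.22 without 240. The p38 call ended without 240, 253, 252 or 262 (0.0591 to 0.248), with medians of -0.20 without 240 and -0.29 without 253, and the DNA repair call without 240, 253, 265 or 252 (0.0788 to 0.115), with medians of -0.17 without 265 and -0.27 without 252. The p38 and DNA repair calls also ended with upper-quartile scaling (0.0745 and 0.0773), with the length trend removed (0.0575 and 0.149) and without 253 and 265 together (0.22 and 0.435). The FLT3/STAT5 call ended with the share of reads outside genes as a covariate (0.124).

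By gene, edgeR called 0 of 16639 genes after treatment in the WT niche, with a smallest adjusted p of 0.0849. Among the named genes with the smallest p, Cc2d1b, Sipa1, Vcp and Kmt2d had log2 fold changes of -2.75 ± 0.46, -2.25 ± 0.41, -1.31 ± 0.25 and -1.66 ± 0.31, and Mcts1 and Mtch2 of 1.68 ± 0.29 and 1.51 ± 0.28, all with an adjusted p of 0.172. At an unadjusted p under 0.05 there were 3035 genes (18.2%). DESeq2 called 1069 genes (499 higher, 570 lower) and limma voom 0. Without 257 or 240, edgeR called 1012 (564 higher, 448 lower) or 190 genes (156 higher, 34 lower). The groups did not overlap for 27.7% of genes, against 10% by chance on average over all splits, and an excess over chance was not tested.

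**Figure D3:**
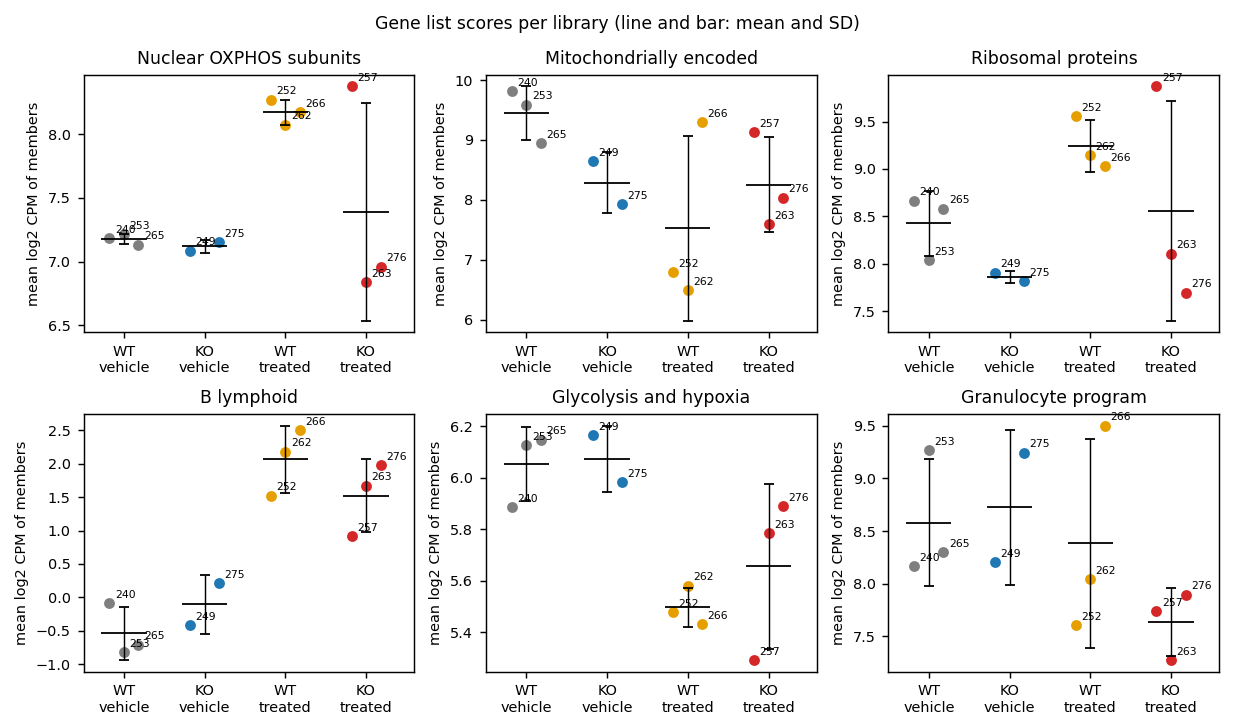
Mean log2 CPM of the measured members of 6 gene lists in each library, by group. Points are libraries, lines are group means and bars are SD. WT treated libraries lie above WT vehicle libraries for nuclear oxidative phosphorylation, where the median log2 fold change was 1.08.

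Treatment in the KO niche was measured in 3 treated and 2 vehicle libraries. All 76 ribosomal protein genes were higher after treatment, with a median log2 fold change of 1.02, Rps12 at 1.86 ± 0.73 and Rpl30 at 1.67 ± 0.69. Granulocyte genes were lower, with a median of -1.0 (25 of 27 negative). Ltf, a neutrophil granule protein, was at 469 CPM ± 121 (SD, n = 3) after treatment and 2318 CPM ± 1444 (n = 2) with vehicle, and Cd177 at 88.4 CPM ± 50.9 and 535 CPM ± 312. Erythroid genes had a median of 1.95 (19 of 19 positive), with Blvrb at 375 CPM ± 237 and 97.0 CPM ± 103. Glycolysis genes had a median of -0.45 (26 of 31 negative), with Gpi1 at 616 CPM ± 170 and 1407 CPM ± 70.3 and Aldoa at 499 CPM ± 65.1 and 876 CPM ± 44.8. Megakaryocyte genes had a median of -1.24, with Pf4 at 7.01 CPM ± 7.55 and 127 CPM ± 177 and Ppbp at 0.725 CPM ± 0.231 and 126 CPM ± 177. These 5 lists passed with the preset correlation (adjusted p = 1.18e-13, 1.18e-13, 7.25e-09, 4.24e-07 and 1.45e-05). With an estimated correlation the adjusted p was 0.845, 0.327, 0.373, 0.327 and 0.327. Of the megakaryocyte genes 3 passed when adjusted over the list alone, none of the other 4 lists held any, and 0 passed over all genes. Without KO treated 257 the ribosomal call ended with a median of 0.02 (adjusted p = 0.832). The erythroid median was 1.15 without 249, 3.96 without 275 and 0.71 without 276. Without KO vehicle 275 the megakaryocyte call ended with a median of 0.39 (adjusted p = 0.848), and without 249 or 263 the median was -2.04 or -1.87.

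The B lymphoid, T and NK and interferon lists were higher after treatment in the KO niche, where the treated libraries were again the deeper ones. The B lymphoid list had a median log2 fold change of 2.07, or 1.61 with 4 members at 0 in a group at their bound, with Igkc at 202 CPM ± 216 and 8.88 CPM ± 7.06 and Jchain, the joining chain of secreted antibodies, at 69.3 CPM ± 103 and 1.97 CPM ± 0.450. The T and NK cell list had a median of 1.48 (21 of 26 positive) and the interferon list 0.69, with Isg15 at 119 CPM ± 101 and 9.61 CPM ± 6.31 and Ifi27 at 148 CPM ± 101 and 50.1 CPM ± 6.66. The haematopoietic stem cell list had a median of 0.69 (30 of 38 positive), with Mllt3, a regulator of stem cell maintenance, at 28.5 CPM ± 12 and 4.35 CPM ± 1.60. Oxidative phosphorylation genes had a median of 0.60, and the ATF4, CXCL12/CXCR4 and p38 lists -0.38, -0.23 and -0.20, while the mean of the CXCL12/CXCR4 list was 0.28. Mapk14 was at 153 CPM ± 68.9 after treatment and 224 CPM ± 11.3 with vehicle, Cdkn1a at 40.3 CPM ± 33.8 and 23.3 CPM ± 5.80 (a log2 fold change that was -0.15 without 257 and 1.19 without 276), and Pola1, of DNA replication, at 111 CPM ± 30.5 and 46.1 CPM ± 1.34. With the preset correlation the first 5 of these lists rose (adjusted p = 1.46e-05, 0.00055, 0.00123, 0.047 and 0.00806) and the last 3 fell (0.00254, 0.00797 and 0.0126). With an estimated correlation the adjusted p was 0.322, 0.327, 0.912, 0.912, 0.912, 0.327, 0.813 and 0.813. Adjusted over the list alone 2 B lymphoid genes passed, none of the other 7 lists held any, and 0 passed over all genes.

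Leaving out 1 library changed most of these smaller lists. Without KO vehicle 249 the T and NK, interferon and oxidative phosphorylation calls ended (adjusted p = 0.0586, 0.291 and 0.0649), with a T and NK median of 0.97, and the CXCL12/CXCR4 median was -0.40. Without KO vehicle 275 the stem cell, oxidative phosphorylation, ATF4 and CXCL12/CXCR4 calls ended (adjusted p = 0.498, 0.0887, 0.0675 and 0.0970), with an ATF4 median of -0.24, and the B lymphoid, T and NK and interferon medians were 3.88, 6.42 and 1.33. Without KO treated 257 the CXCL12/CXCR4 and p38 calls ended (adjusted p = 0.719 and 0.635), with medians of -0.07 and 0.14, and the oxidative phosphorylation median turned to -0.18 and passed as lower (adjusted p = 1.05e-07). The same omission moved the stem cell and ATF4 medians to 0.45 and -0.25. Without KO treated 263 the ATF4 and stem cell calls ended (0.0545 and 0.86), with a stem cell median of 0.10, and the CXCL12/CXCR4 and oxidative phosphorylation medians were -0.37 and 0.95. Without KO treated 276 the T and NK, CXCL12/CXCR4, oxidative phosphorylation and p38 medians were 0.95, -0.45, 0.91 and -0.43. The stem cell call also ended without WT vehicle 240 (0.0596) or WT treated 266 (0.0593) and with upper-quartile scaling (0.0536). The oxidative phosphorylation call ended with the length trend removed (median 0.07, adjusted p = 0.782) and without 253 and 265 together (0.171).

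By gene, edgeR called 0 of 16639 genes after treatment in the KO niche, with an adjusted p of 1 throughout, and 612 genes had an unadjusted p under 0.05 (3.68%). Serpine2, a protease inhibitor, was at 18.7 CPM ± 8.43 after treatment and 110 CPM ± 42.7 with vehicle, and Pla2g16, a phospholipase, at 101 CPM ± 39.6 and 24.7 CPM ± 5.87. DESeq2 called 23 genes (20 higher, 3 lower) and limma voom 0. The groups did not overlap for 22.4% of genes, against 20% by chance on average over all splits, and an excess was not tested.

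The treatment effect averaged over niches used all 11 libraries, and 14 of the 34 lists passed camera with the preset correlation, 7 higher and 7 lower, against 0 with an estimated correlation (smallest adjusted p 0.156), 3 with fry and 0 by permutation. By permutation no list can pass over 34 lists unless others also reach small p-values. B lymphoid genes had a median log2 fold change of 3.46 (2.52 without the 6 members at 0 in a group, 18 of 19 positive), with Igkc at 3.72 ± 0.72 and Blnk at 3.70 ± 0.99. The T and NK list had a median of 1.65, or 0.84 without the 8 members at 0 in a group. The glycolysis list had a median of -0.58 (26 of 31 negative), with Hk1, Gpi1 and Pkm at -0.90 ± 0.29, -1.04 ± 0.30 and -0.88 ± 0.26. The p38 list had a median of -0.26 and a mean of 0.15, with Mapk14 at -0.94 ± 0.27 and Mapkapk2 at -1.16 ± 0.33. Cdkn1a, Isg15, Mcts1 and Tyms, which makes thymidylate, had log2 fold changes of 1.41 ± 0.57, 2.82 ± 0.73, 1.20 ± 0.22 and 0.97 ± 0.24. With the preset correlation the first 2 lists rose (adjusted p = 6.03e-07 and 0.0018) and the glycolysis and p38 lists fell (3.14e-09 and 0.00441). With an estimated correlation the adjusted p was 0.156, 0.59, 0.237 and 0.684. The B lymphoid, T and NK and glycolysis lists passed fry (adjusted p = 0.00666, 0.0381 and 0.0381). Adjusted over the list alone 9 B lymphoid and 1 T and NK gene passed, none of the others did, and 0 passed over all genes. The T and NK median was 2.87 without 240 and 3.15 without 275, its call ended with the share of reads outside genes as a covariate (adjusted p = 0.0553), and the p38 median was -0.10 without 253, -0.15 without 257 and -0.40 without 276. By gene, edgeR called 0 of 16639 (smallest adjusted p 0.251, with 2668 genes at an unadjusted p under 0.05), DESeq2 425 (243 higher, 182 lower) and limma voom 1.

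Another 10 lists passed for the averaged treatment effect. Ribosomal protein, nuclear oxidative phosphorylation, interferon, antigen presentation and erythroid genes rose with the preset correlation, with medians of 0.94, 0.89, 0.81, 0.64 and 0.92 (adjusted p = 3.05e-12, 2.84e-10, 0.00203, 0.00612 and 0.0123). Granulocyte, mitochondrially encoded, CXCL12/CXCR4, DNA repair and FLT3/STAT5 genes fell, with medians of -0.45, -0.69, -0.39, -0.22 and -0.49 (adjusted p = 5.25e-07, 1.9e-05, 1.9e-05, 0.0182 and 0.0236). In the same order the adjusted p with an estimated correlation was 0.728, 0.727, 0.728, 0.728, 0.728, 0.684, 0.727, 0.59, 0.727 and 0.59, and 0 members of these 10 lists passed when adjusted over the list alone or over all genes. Without 257 the ribosomal and oxidative phosphorylation medians were 0.46 and 0.40. The interferon call ended without 249 (0.081), and its median was 1.66 without 240, 1.28 without 275 and 0.46 without 252. The antigen presentation call ended without 265 (0.0708), and its median was 0.41 without 252. The erythroid call ended without 253 (0.0911), 249 (median 0.54, adjusted p = 0.457) or 276 (0.37, 0.37), and its median was 1.87 without 275. The granulocyte median was -0.22, -0.83, -0.24, -0.90 and -0.79 without 253, 249, 275, 266 and 257, and the mitochondrially encoded median -0.46 without 249 and -1.49 without 266. The CXCL12/CXCR4 median was -0.25 without 253. The DNA repair call ended without 265 (0.0532) or 257 (median -0.07, adjusted p = 0.0733), and its median was -0.11, -0.13, -0.13 and -0.40 without 253, 275, 266 and 276. The FLT3/STAT5 call ended without 240 (median -0.26, adjusted p = 0.0806), 249 (-0.22, 0.081) or 276 (0.0747). With the length trend removed the ribosomal median was 0.14, and the oxidative phosphorylation (0.13, 0.304) and DNA repair calls (0.0596) ended. Leaving out 253 and 265 ended the antigen presentation, interferon, erythroid and DNA repair calls (0.453, 0.797, 0.0784 and 0.11) and turned the granulocyte median to 0.09 (adjusted p = 0.0109), and the covariate ended the antigen presentation, erythroid, mitochondrially encoded and FLT3/STAT5 calls (0.0527, 0.374, 0.0594 and 0.1).

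**Figure D4:**
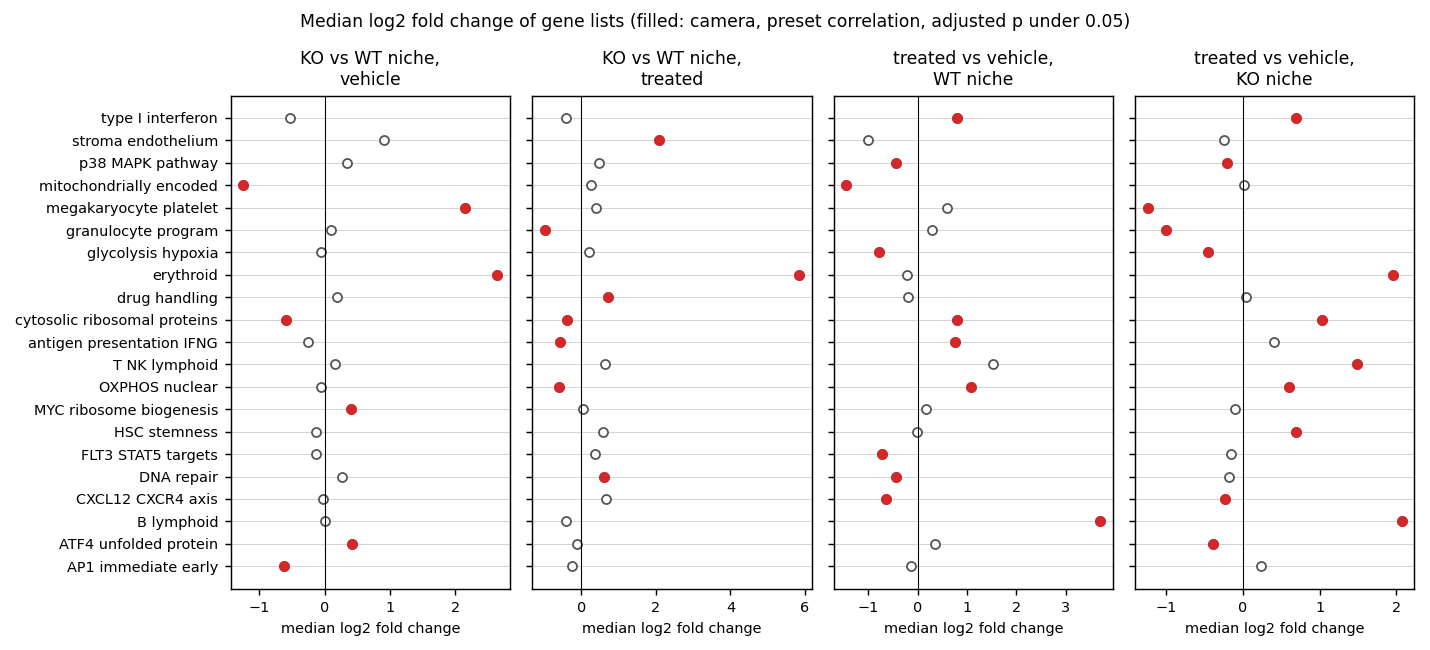
Median log2 fold change of each gene list that passed in at least 1 of the 4 comparisons drawn. Filled points passed camera with the preset correlation, and none passed with an estimated correlation. The erythroid list stands at 5.84 between the treated niches and 2.65 between the vehicle niches.

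The interaction asks whether the niche changed the response to treatment. By gene, edgeR called 0 of 16639 genes, with a smallest adjusted p of 0.628 and 1050 genes at an unadjusted p under 0.05. DESeq2 called 58 (24 higher, 34 lower) and limma voom 0, and edgeR called 1 without 240. Rb1cc1, which starts autophagy, and Abcb4 had log2 differences of 1.99 ± 0.46 and 4.05 ± 1.0, Clu of -6.01 ± 1.56, Cycs of -1.55 ± 0.56 and Mapk14 of 0.78 ± 0.55. Across 16639 genes, the treatment effects in the WT and KO niches, which share no library, had a Pearson r of 0.187 (Spearman 0.237). The niche effects in vehicle and treated hosts had an r of 0.172 (Spearman 0.186), and genes are not independent replicates.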

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

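The tests of reads outside genes, of a wrong label, of erythroid cells, of single libraries in vehicle hosts and of splits at an unadjusted p were chosen after the result they measure had been seen. KO treated library 257 resembled the WT treated libraries more than its own group. Its profile relative to the mean of all libraries had a mean correlation across genes of 0.543 with the 3 WT treated libraries and -0.387 with the other 2 KO treated libraries, and its Mapk14 level was 74.7 CPM against 65.1 to 80.0 CPM in WT treated and 179 and 205 CPM in 263 and 276. A trend with transcript length as the whole cause is argued against, because the difference between these correlations was 0.67 after the trend of each library was removed, above the 0.3 set in advance. Reads outside genes, at 30.4%, lay above the highest WT treated library (16.6%), which argues against a shared share of such reads. A wrong niche label cannot be told apart from a true difference between hosts: the erythroid score of 7.64 lay near 263 and 276 (7.30 and 9.75) and above WT treated (2.77 to 3.36), but the genotype of the host cannot be read from sorted cells. A biological difference between KO treated hosts stays open and was not tested.

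Erythroid genes were higher in KO niches, with a median log2 fold change of 4.49 averaged over treatment, and library scaling, the transcript length trend and any single library are argued against as whole causes of that average: the lowest median under the other scalings was 4.34, that with the length trend removed 4.17, and the lowest without 1 library 3.08 (without KO vehicle 275). In vehicle hosts alone the median of 2.65 was 0.55 without 275. KO vehicle 249, with a score of 4.18, lay near WT vehicle 240 and 265 (3.59 and 3.43) and above 253 (0.855). Much of the vehicle difference, though not all of it, therefore rests on library 275. Of the 200 arrangements of the libraries within treatment, 1 gave a difference in erythroid score as large, the real one, at 4.20 against 4.07 for the highest of the others. The permutation was chosen after the data were seen. Its p of 0.005 for this list taken alone is the smallest that 200 arrangements can give. After adjustment over 34 lists it was 0.132. A list at the smallest p cannot pass this adjustment unless other lists also reach small p-values. The adjusted value therefore cannot decide about chance, which is not excluded. Erythroid cells or their RNA among the sorted cells cannot be told apart from an erythroid programme within them, the biological alternative that the niche label gives, and a stem cell sort normally removes cells with erythroid markers. Either would give what was seen: 18 of the 19 members, 14 of them outside the 4 globin genes and 0 shared with another list, were higher in each KO treated library than in every WT treated library, globin took up to 10.5% of counts and Alas2 reached 1247 CPM on average.

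After treatment in the WT niche, nuclear oxidative phosphorylation genes had a median log2 fold change of 1.08 and ribosomal protein genes 0.80. With the length trend of each library removed these medians were 0.14 and -0.18, so that a length bias of the libraries may account for most of both. The WT treated libraries had rho values from -0.34 to -0.59 with transcript length and the WT vehicle libraries 0.11 to 0.24, and both lists hold short transcripts, with median lengths of 1231 and 1100 nucleotides. The cause of the length trend was not tested, and a response to treatment that favours short transcripts stays open, since the trend runs with the group. The 13 mitochondrially encoded genes, also short, moved the other way and had a median of -2.31 with the trend removed.

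For the count of genes past the threshold, other groupings of the same libraries were fitted with edgeR. The real count was 0 in each contrast, so every split gave as many (10 of 10 for the treated niches and for treatment in WT, 100 of 100 for each averaged effect) and these counts decide nothing, with highest other counts of 0, 0, 10 and 0. At an unadjusted p under 0.05, 10 of the 100 splits drawn, the real one included, gave as many genes as the 1811 of the mean niche effect (highest other 2265). The splits with 2265 and 1827 kept the KO treated and WT treated libraries apart, with the labels kept or swapped. Most of the rest kept 263 and 276 on the same side. Such splits hold part of the niche difference themselves, so this share cannot decide about chance, which is not excluded there. For the 2668 genes of the mean treatment effect, 5 of 100 splits gave as many, the real one included (highest other 3729). Each of the others among these 5 kept the WT treated and WT vehicle libraries apart, with the labels kept or swapped. They hold the WT treatment difference themselves, so this share cannot decide about chance. The 10 possible splits of 6 libraries are too few for a share under 0.05. Between the treated groups the real and highest other counts were 1769 and 2071 unadjusted, 226 and 224 with DESeq2 and 4375 and 3697 with limma voom, whose next splits had 3327 and 3130, and all 3 of these splits joined 257 to 2 WT treated libraries, which points to a structure of the samples around 257. For treatment in the WT niche they were 3035 and 1502 unadjusted, 1069 and 305 with DESeq2 and 0 and 15 with limma voom.

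The treatment effect differed between niches for 7 gene lists by the interaction test with the preset correlation, and each had an adjusted p of 0.975 with an estimated correlation. The mitochondrially encoded list had a difference of 1.65 (medians of -1.44 in WT and 0.01 in KO niches, adjusted p = 1.98e-06), which was 3.19 without 266 and 0.92 without 257. The nuclear oxidative phosphorylation list had a difference of -0.58 (1.08 and 0.60, adjusted p = 9.43e-06), which was -1.25 without 257, -0.32 without 276 and no longer passed without 263 (-0.24, adjusted p = 0.0531). The erythroid list had a difference of 2.59 (-0.21 and 1.95, adjusted p = 1.98e-05), which was 4.55 without 275, 1.44 without 276 and did not pass without 249 (1.60, adjusted p = 0.116). The megakaryocyte list had a difference of -1.69 (0.60 and -1.24, adjusted p = 0.000135), or -0.77 without the 4 members at 0 in a group, which was -5.14 without 240 and did not pass without 275 (-0.29, adjusted p = 0.212). The granulocyte list had a difference of -1.21 (0.30 and -1.0, adjusted p = 0.0104) and did not pass without 240, 265, 275, 266 or 263 (adjusted p from 0.0531 to 0.807), with differences of -0.66 without 275 and -0.15 without 266. The AP-1 list had a difference of 0.60 (-0.13 and 0.23, adjusted p = 0.031) and did not pass without 240, 253, 249, 262 or 257 (0.0724 to 0.228), with differences of 0.32 without 240 and 0.28 without 249. The ATF4 list had a difference of -0.43 (0.36 and -0.38, adjusted p = 0.031) and did not pass without 240, 265, 275, 262, 266, 257 or 263 (0.0501 to 0.156), was -0.68 without 276, and with the length trend removed turned to 0.0461 and did not pass (adjusted p = 0.402, or 0.826 without 257 as well). The length trend removed also ended the oxidative phosphorylation and granulocyte calls (-0.08 and -0.70, adjusted p = 0.486 and 0.2), upper-quartile scaling the AP-1 call (0.0522), and leaving out 253 and 265 the megakaryocyte and ATF4 calls (0.0825 and 0.0825). With the share of reads outside genes as a covariate the mitochondrially encoded, megakaryocyte, granulocyte, AP-1 and ATF4 differences did not pass (adjusted p = 0.115, 0.12, 0.115, 0.594 and 0.408).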

How the results depend on the processing

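The settings that remove the length trend, use the share of reads outside genes, leave out 253 and 265 together, or permute list scores were chosen after the data were seen. Of 2976 log2 fold changes of named genes under all settings, 2961 kept their direction, 15 turned and 270 passed the threshold, which no named gene did at first. Most of these genes were chosen for a small p in the same libraries, and the settings refit the same counts. A kept direction was therefore likely in advance and is not independent support. Genes called by edgeR went from 0 in each comparison to the following counts, given as KO against WT treated, KO against WT vehicle, treatment in WT, mean niche effect and mean treatment effect. Without a filter they were 43, 11, 215, 83 and 7, and with a mean CPM of at least 10 the mean niche effect had 2. DESeq2 gave 226, 206, 1069, 371 and 425, and 23 for treatment in KO and 58 for the interaction, in a tool that made 95 to 117 false calls in data simulated with the estimated spread and 58 to 67 with 0.25 of it (edgeR 3 to 8 and 8 to 11). The simulation held no structure shared between libraries, so these false calls may not carry over to the real data. With limma voom the counts were 4375 (KO against WT treated), 545 (mean niche effect) and 1 (mean treatment effect), with weights of 0.241 for library 257 and 0.247 for 253. Leaving out 1 library gave 0 to 1513 genes for KO against WT treated, 0 to 1012 for treatment in WT, 0 to 1000 for the mean niche effect (each highest without 257), 0 to 85 for KO against WT vehicle and 0 to 1 for the interaction (both highest without 240), and 0 for treatment in KO and for the mean treatment effect. The covariate gave 2100 for treatment in WT and 1517 for the mean treatment effect, and the length trend removed without 257 gave 43 for KO against WT treated and 74 for the mean niche effect. Leaving out 253 and 265 together gave 0 in each comparison. Correlations of effects across genes rose from 0.187 and 0.172 to 0.35 (treatment) and 0.36 (niche) with a mean CPM of at least 10, which tests fewer genes. Leave-one-out values were 0.10 to 0.23 and 0.07 to 0.19.

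Lists past the threshold numbered 8, 7, 11, 13, 7, 14 and 14 over the 7 contrasts (KO against WT treated and vehicle, treatment in WT and KO, interaction, mean niche and mean treatment effect). With an estimated correlation there were 0 in each, with fry 0 except 1 for treatment in WT and 3 for the mean treatment effect, and with permutation 0 in the 6 contrasts tested, of which the 4 within 1 stratum cannot reach a p under 0.1. In the averaged contrasts the smallest permutation p is 0.005, at which a list cannot pass over 34 lists unless others reach small p-values too. With the length trend removed there were 6 for the mean niche effect, and without 257 as well 5 for KO against WT treated and 6 for the mean niche effect. The covariate gave 7 for treatment in WT and 9 for the mean treatment effect, and leaving out 253 and 265 gave 14 for KO against WT vehicle. Leaving out 1 library gave 5 to 11 lists for KO against WT vehicle, 6 to 13 for treatment in WT and 7 to 14 for the mean niche effect. The erythroid medians of 5.84 (treated) and 4.49 (mean niche effect) did not pass with an estimated correlation or fry (adjusted p = 0.311 and 0.323, and 0.31 and 0.167), nor did the score differences of 5.21 and 4.20 by permutation (0.618 and 0.132), and leaving out 1 library gave 4.22 to 6.39 and 3.08 to 5.21. List medians that turned were, with the covariate, ribosomal proteins 0.16 (KO against WT vehicle). With the length trend removed, with and without 257, they were ribosomal proteins -0.18 and -0.18 (treatment in WT) and ATF4 0.0461 and 0.0444 (interaction), and without 257 also ribosomal proteins -0.0158 and oxidative phosphorylation -0.21 (treatment in KO), -0.0813 and -0.0225 (mean treatment effect) and ribosome assembly -0.0265 (mean niche effect). With 257 kept, G2/M was -0.0365 (mean niche effect). The list scores used for permutation had p38 at 0.18 and DNA repair at 0.13 (treatment in WT), and without 253 and 265 interferon genes were at -0.43 (treatment in WT) and granulocyte genes at 0.00164 (mean niche effect) and 0.0883 (mean treatment effect). Leaving out 1 library gave -0.21 to 1.77 for interferon genes (treatment in WT) and, for treatment in KO, -2.04 to 0.39 for megakaryocyte genes, -0.18 to 0.95 for oxidative phosphorylation and -0.43 to 0.14 for p38. Single genes that turned were Cxcr4 (0.10 and 0.40) and Tet2 (-0.37) with the length trend removed, Tet2 with upper-quartile scaling (-0.0433) and without 1 library (-0.28 to 0.73), and Mapk14 in KO against WT vehicle (-0.16 with the covariate, -0.16 and -0.15 with the length trend removed). Leaving out 1 library gave -1.46 to 5.39 for Pf4 in KO against WT vehicle and, for treatment in KO, -5.59 to 1.71 for Pf4, -8.45 to 0.27 for Ppbp and -0.15 to 1.19 for Cdkn1a, which was -0.19 with the length trend removed without 257. Upper-quartile scaling moved the median of all genes by -0.16 (KO against WT treated), 0.23 (treatment in WT), -0.15 (interaction) and 0.15 (mean treatment effect). Where a setting did not itself reduce the samples or genes, the cause was not tested.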

Other observations

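The ranges below were put together after the list tests had been seen. Lists of 13 kinds passed in none of the 4 comparisons between single groups, although therapy that damages DNA would be a reason to look at them: p53 targets, S phase, G2/M, quiescence and CDK inhibitors, BCL2 family, NRF2, heat shock, NF-kB, ERK output, TGF-beta and BMP, monocytes, mast cells and sex-linked genes. Of these, S phase, G2/M and monocyte genes passed only for the niche effect averaged over treatment. After treatment in the WT niche their adjusted p lay between 0.188 and 0.945 with the preset correlation, with medians from -1.07 (sex-linked genes) to 1.03 (mast cells). In the KO niche the range was 0.246 to 0.944, with medians from -0.18 (TGF-beta and BMP) to 0.78 (sex-linked genes). Between the niches the adjusted p was 0.114 to 0.94 in treated hosts, with medians from -0.52 (monocytes) to 0.89 (ERK output), and 0.0904 to 0.987 in vehicle hosts, with medians from -0.58 (sex-linked genes) to 0.49 (ERK output). The median, the mean and the test of a list differed in sign for 6, 2, 3 and 0 of these lists in the same order.

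Xist, which female cells express, and Y-linked genes were both detected in most libraries. Xist was at 0 in WT vehicle 253 and between 9.91 CPM (266) and 103 CPM (257) in the other 10, and Ddx3y was between 7.65 CPM (275) and 66.5 CPM (253) in all 11. Whether the libraries held cells of both sexes was not tested.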
